A study of Mus musculus with 6 samples.

How the data were processed

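Transcript levels were measured by RNA sequencing in sorted haematopoietic stem cells of 4-month-old female mice, in 3 libraries labelled control and 3 labelled Thbs1 knockout. Per the labels' protocols, cells were sorted into a phenol reagent, and 2 ng of total RNA per library entered the SMART-Seq v4 ultra low input kit, which primes cDNA from poly(A) tails and does not mark strand. Sense and antisense reads of overlapping genes therefore cannot be told apart. The submitters' processing notes name FastQC 0.11.5, STAR and edgeR, and the mouse genome builds GRCm38 and mm10. What each tool was used for, the annotation and the counting rules are not given in the sources used here.

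The deposited table holds FPKM values, made by the authors, for 52183 genes in the 6 libraries with 2 decimals. The unit is given by the name of the deposited table, and its values bear the steps of FPKM; the header names the library of each column. All 52183 Ensembl identifiers matched GENCODE release M21 (GRCm38), from which positions, gene types and merged exon lengths were taken. Symbols come from the deposited table. Summed over all genes, FPKM multiplied by exon length came to between 1.067 and 1.069 times what the definition of FPKM gives, in every library, so the values show no further scaling factor that differs between libraries.

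Depth was read from the FPKM values. For genes with at most 400 bp of exon, values are multiples of what 1 read is worth, and the depth that made most of them whole was taken. Between 99.4% and 99.8% of these values were then whole within 0.1 read, and the depths came to between 22710000 and 30900000 reads. Intervals and floors that follow from such read numbers cover counting error only, because reads amplified by PCR without molecular identifiers are not independent molecules. Replicates were compared before averaging: between any 2 libraries of a group, chi-square per degree of freedom over genes of up to 3000 bp with at least 20 reads lay between 8.06 and 15.6, so no library was a copy of another.

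Because FPKM are not counts, genes were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, two-sided). Genes with at least 1 FPKM in at least 3 of the 6 libraries entered, 12555 in all. The group was the single term of the model, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 changes are knockout-labelled minus control-labelled values on the log2(FPKM + 1) scale, which understates the change of low genes, and their errors are limma's moderated standard errors. Levels are means of FPKM with the SD over 3 libraries. Thbs1 was also compared by an exact permutation test of its FPKM.

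Before the data were examined, 29 gene lists with 862 entries were fixed, covering stem cell programmes, signalling, stress, metabolism, other bone marrow cell types and genes beside Thbs1. The 26 lists with at least 5 tested members were tested against all other genes with camera, at a preset correlation of 0.01 and at an estimated correlation. Fry tested each list against no change, without comparing it with other genes. The rule for named genes was fixed at the same time: Thbs1, the 12 largest rises and 12 largest falls among called genes whose groups do not overlap, leaving out unnamed gene models, and up to 4 members of each list with the smallest unadjusted p. Some genes that the rule selected are not reported here. Dnajb1 and Eif3j1, and other genes where the text says so, lie outside this rule and were chosen after their values were seen.

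Data were simulated with the means of these libraries and limma's moderated variances, as normal values independent between genes. On them the test recovered 71.8% of 78 genes changed 1.5-fold, 96.2% of 52 changed 2-fold and 97.1% of 70 changed 4-fold. Among 12318 genes tested there were 8 false calls among 182. These are folds of FPKM + 1, given only to genes with a mean above 1 on the log2(FPKM + 1) scale. Recovery of the lowest genes was therefore not measured. Real libraries may not vary in this way, so recovery may be lower and false calls more frequent there. In a second simulation, camera with the preset correlation called the 1 list of 30 genes shifted by 0.5 on the log2 scale and 0 of 20 lists without a shift. Simulated genes varied independently, so this does not test lists of correlated genes.

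Alternatives fixed in advance were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, rescaling to TPM, scaling by the median of ratios, quantile normalization, eBayes without trend, array weights, the replicate number as a block, and leaving out each library. Precision weights from vooma, protein-coding genes alone, and leaving out genes within 20 Mb of Thbs1 were added after seeing the data. Sequence identities were measured with BLAST 2.17.0 on the longest GENCODE transcript of each gene. All 6 libraries and all value columns of the table were used. No count model was run, since the reads recovered from FPKM depend on an assumed exon length for each gene.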

Results

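Gene expression was measured by RNA sequencing in haematopoietic stem cells, the rare bone marrow cells that renew the whole blood system, sorted by flow cytometry from 4-month-old female mice. There were 3 libraries labelled control and 3 labelled Thbs1 knockout. The comparison asks which transcripts of these stem cells differ when Thbs1 is deleted. Each library was made from 2 ng of total RNA with an oligo-dT full-length method for very small inputs. The deposited values are FPKM, fragments per kilobase of exon in every 1000000 mapped fragments, for 52183 genes. The steps between neighbouring FPKM values of short genes correspond to 25950000, 23100000 and 22710000 reads in control libraries 1 to 3 and to 30900000, 26030000 and 25760000 in the libraries labelled knockout 1 to 3. At these depths a single read of a gene with 1 kb of exon is worth between 0.0324 and 0.0440 FPKM, and 3 reads between 0.0970 and 0.132 FPKM. Between 21301 and 28104 genes had a value above 0 in a library, and between 12289 and 12851 reached 1 FPKM. On the log2(FPKM + 1) scale, libraries of the same group correlated across genes at 0.983 to 0.987, and libraries of different groups at 0.977 to 0.983. The first principal component held 33.6% of the variance and separated the 2 groups. The labels do not say that the libraries came from separate animals, so all p-values measure only the spread between these libraries, which may be technical.

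Thbs1 (ENSMUSG00000040152, chromosome 2, 118111876 to 118127133, GRCm38) encodes thrombospondin 1, a secreted matrix glycoprotein that binds CD47 and CD36 and activates latent TGF-beta. It was read at 4.12, 13.8 and 2.33 FPKM in control libraries 1 to 3 and at 10.8, 8.5 and 7.68 FPKM in the libraries labelled knockout 1 to 3. Thbs1 was therefore not lower in the libraries labelled knockout, with means of 6.76 ± 6.18 against 9.0 ± 1.63 FPKM (SD, n = 3 each). The difference lay within the spread of the control libraries (log2 change 0.65 ± 0.43 SE, limma adjusted p = 0.503; exact two-sided permutation p = 0.5, where 3 against 3 cannot go below 0.1). Control library 2 decided this result: without it, Thbs1 was higher in the libraries labelled knockout (log2 change 1.26, adjusted p = 0.0344). Between 321 and 2030 reads lay behind each value, so depth was not limiting. The labels do not say which part of the gene was deleted, and the FPKM sums all its exons, so reads from the remaining exons of a deleted allele would count. The level of Thbs1 thus does not bear out the knockout label, and every direction given here follows the labels alone.

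Haematopoietic stem cells labelled knockout had more transcript of the heat-shock chaperones Hspa8 and Hspa1b, of the glucocorticoid-induced regulator Tsc22d3 and of the growth-promoting transcription factor Myc. Hspa8 rose from 344 ± 20.3 to 620.2 ± 40.7 FPKM (SD, n = 3 each) and Myc from 249 ± 24.1 to 403 ± 18.3 FPKM. Genes that lie near Thbs1 on chromosome 2 changed in both directions, from a 9.81-fold rise of Tmem87a to a fall of Kcnip3 from 7.08 ± 0.490 to 1.63 ± 0.337 FPKM. Transcripts counted on Lars2 and on a set of very short features fell as well. Of 12555 genes tested with limma, 71 were higher and 125 lower in the libraries labelled knockout at an adjusted p below 0.05. Of the higher genes 63 were protein-coding, and of the lower genes 92. Among all called genes, coding or not, 9 of the higher and 33 of the lower changed by at least 1 on the log2(FPKM + 1) scale, a scale that understates the change of low genes. The 2 groups did not overlap in 22.8% of the tested genes, where chance gives 10%, and 2057 genes had an unadjusted p below 0.05, where chance gives 628. The counts fell to between 16 and 38 higher and between 43 and 77 lower when each library was left out in turn. They fell whichever library was left out, and fewer libraries also give the test less power. The fall therefore does not show that particular libraries drove the calls. Rescaled so that every library sums to 1000000 (TPM), the data gave 2016 higher and 128 lower genes, so that 94% of the calls were higher in place of 36.2%. Under TPM genes shifted together by a median of 0.19 on the log2 scale, and 15277 genes were tested in place of 12555. How much each of these added to the calls was not tested.

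**Figure D1:**
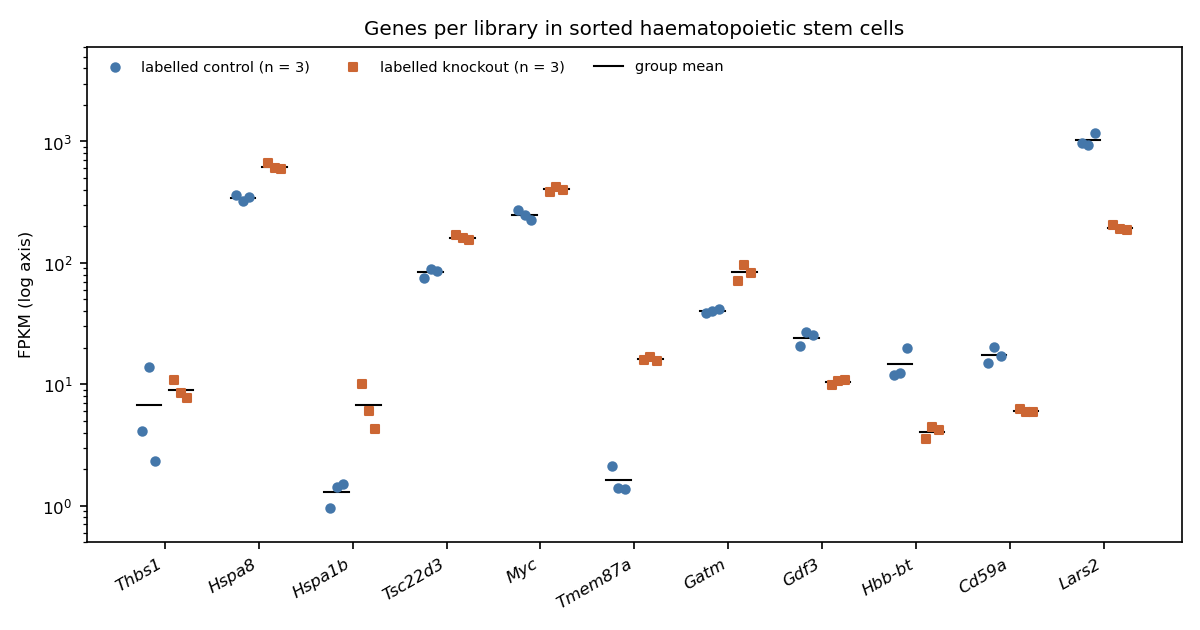
Values of 11 genes in FPKM on a log axis, each point 1 library (circles, labelled control; squares, labelled knockout; bars, group means of 3 libraries). Thbs1 overlaps between the groups, while the other 10 genes do not.

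Among the 12 largest rises outside unnamed gene models, 5 lay within 20 Mb of Thbs1. Tmem87a (ENSMUSG00000033808, chromosome 2, 120355312 to 120404113), a Golgi membrane protein gene, rose from 1.63 ± 0.425 to 15.997 ± 0.576 FPKM (log2 change 2.70 ± 0.13 SE, adjusted p = 1.38e-05). Rpusd2, a pseudouridine synthase gene, rose by 1.53 ± 0.13 (adjusted p = 0.000486), and Gatm, which encodes the first enzyme of creatine synthesis, rose from 40.1 ± 1.65 to 83.6 ± 12.6 FPKM (log2 change 1.03 ± 0.10, adjusted p = 0.00141). Depdc7 (1.09 ± 0.19) and Fjx1 (0.93 ± 0.17) were the other rises of this stretch. Away from Thbs1, Hspa1b (ENSMUSG00000090877, chromosome 17, 34956436 to 34959238), the stress-inducible HSP70, rose from 1.29 ± 0.299 to 6.78 ± 2.99 FPKM (log2 change 1.70 ± 0.25, adjusted p = 0.0112), and Hsph1, a nucleotide exchange factor of HSP70, from 10.6 ± 1.18 to 20.8 ± 2.20 FPKM (0.91 ± 0.11, adjusted p = 0.00383). Hspa1b shares near-identical coding sequence with Hspa1a, so the split of reads between the pair is uncertain. Tsc22d3 (ENSMUSG00000031431, chromosome X, 140539528 to 140600659) rose from 83.6 ± 7.46 to 162 ± 7.66 FPKM (0.94 ± 0.08, adjusted p = 0.000512). Banp, a nuclear-matrix DNA-binding protein gene (1.00 ± 0.15), and Ramp2, a co-receptor for adrenomedullin (0.92 ± 0.16), rose as well. The largest fitted rise was that of Pcna-ps2, a processed pseudogene of Pcna on chromosome 19, from 3.41 ± 0.590 to 45.6 ± 1.99 FPKM, and Eif3j2, a near-copy of Eif3j1 on chromosome 18, rose from 0.390 ± 0.0361 to 7.08 ± 1.22 FPKM. Their sequences are 99.2% and 99.4% identical to their parents Pcna and Eif3j1 over 781 and 2379 aligned bases, so which locus gave these reads is uncertain.

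Among the 12 largest falls, 3 lay within 20 Mb of Thbs1. These were Kcnip3, a calcium-binding regulator of potassium channels (log2 change -1.62 ± 0.14, adjusted p = 0.000512), the nucleoside transporter gene Slc28a2 (-1.42 ± 0.13, adjusted p = 0.000921) and Cd59a, which encodes a membrane inhibitor of complement (-1.39 ± 0.11, adjusted p = 0.000486). Gdf3 (ENSMUSG00000030117, chromosome 6, 122605403 to 122610087), a ligand of the TGF-beta superfamily, fell from 24.2 ± 3.27 to 10.4 ± 0.440 FPKM (-1.13 ± 0.11, adjusted p = 0.000921), and Mc5r, a melanocortin receptor gene, from 19.1 ± 3.15 to 8.47 ± 1.17 FPKM. Clnk, an adaptor of immunoreceptor signalling, and Bex6 fell by 1.20 and 1.46 on the log2 scale. Hbb-bt, an adult beta-globin gene, fell from 14.8 ± 4.50 to 4.06 ± 0.462 FPKM, though reads of the closely related globin gene Hbb-bs may be split with it. Lars2 (ENSMUSG00000035202, chromosome 9, 123366927 to 123462666) encodes the mitochondrial leucyl-tRNA synthetase. Reads counted on it fell from 1024 ± 125 to 194 ± 10.6 FPKM (-2.39 ± 0.10, adjusted p = 3.65e-06), or from 1.14% to 0.215% of all reads. Very short features fell with it, so whether these reads came from its messenger RNA is uncertain and was not tested. The short microRNA feature Mir6236 fell from 1949 ± 198 to 469 ± 54.5 FPKM, and the small nuclear RNA gene Rn7sk, whose product holds back transcription elongation, from 21.4 ± 4.06 to 6.06 ± 2.17 FPKM. The mitochondrial gene mt-Nd3 fell from 5.33 ± 0.316 to 0.14 ± 0.07 FPKM, with 1 to 47 reads behind its values. A nuclear pseudogene with 99.7% identical sequence over 345 bases makes the level of mt-Nd3 uncertain. Of these 24 genes, 19 stayed past the threshold in every fit with a library left out that tested them. Banp, Clnk, Depdc7, Fjx1 and Ramp2 did not, with adjusted p reaching 0.0586, 0.0653, 0.0968, 0.118 and 0.104. Under the settings that kept all libraries, 12 of the 24 stayed past the threshold in every fit that tested them. Of the 19, Bex6, Gatm, Hbb-bt, Hspa1b, Hsph1, Mc5r and Rn7sk lost it in at least 1 such setting.

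Few genes of haematopoietic stem cell identity were called, and those called changed in both directions. Of 37 measured members, 2 fell and 1 rose. Ly6a, which encodes the stem cell antigen Sca-1, fell from 115 ± 6.78 to 76.9 ± 11.1 FPKM (adjusted p = 0.0286). Ndn, a growth suppressor, rose from 13.2 ± 1.48 to 20.3 ± 2.44 FPKM (adjusted p = 0.0357), and 34 members were not called. Procr, the endothelial protein C receptor of dormant stem cells, stood at 45.4 ± 1.93 and 59.3 ± 7.04 FPKM without passing the test (adjusted p = 0.0857). There were 2 higher and 2 lower members when adjusted over the list alone. Of 18 quiescence genes and cyclin-dependent kinase inhibitors, 3 rose and 15 were not called: Ndn, Egr1, an immediate early transcription factor (10.5 ± 1.24 to 16.7 ± 1.76 FPKM), and Txnip, an inhibitor of thioredoxin (313 ± 17.8 to 463 ± 66.0 FPKM). When adjusted over the list alone, 5 were higher and 0 lower. Of 31 genes that are higher in aged stem cells, the platelet adhesion receptor gene Selp fell from 15.9 ± 1.41 to 8.76 ± 1.47 FPKM (adjusted p = 0.0153), whereas the glutathione transferase gene Gstm2 rose from 10.6 ± 0.517 to 18.5 ± 2.98 FPKM (adjusted p = 0.0159) and Ramp2 rose too. The other 28 were not called, and adjusted over the list alone 5 were higher and 4 lower. These 3 lists were not called by camera, which asks for a common direction against all other tested genes (adjusted p = 0.430, 0.167 and 0.928). An unadjusted p below 0.05 was reached by 12 of 37, 5 of 18 and 10 of 31 members, against 2057 of all 12555 tested genes. Fry's test for change in either direction, which makes no comparison with other genes, called these 3 lists (fry adjusted p = 2.74e-05, 6.45e-05 and 6.45e-05).

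Markers of multipotent progenitors, the next stage after the stem cell, leaned lower. All 9 measured members had fitted changes below 0, with a median of -0.17 on the log2 scale, and 2 passed the test. Ikzf1, which encodes the lymphoid transcription factor Ikaros, was among them and fell from 29.1 ± 1.42 to 20.02 ± 2.46 FPKM (adjusted p = 0.0321). Flt3, the cytokine receptor that marks lymphoid-primed progenitors, stood at 8.96 ± 0.791 and 6.80 ± 0.645 FPKM (adjusted p = 0.149), and Spi1, which encodes PU.1, at 33.5 ± 0.590 and 29.7 ± 0.988 FPKM. When adjusted over the list alone, 0 were higher and 3 lower. Camera called the list with its preset correlation (adjusted p = 0.000234), and the call was lost with the correlation estimated from the data (adjusted p = 0.646 with an estimated correlation).

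Inflammatory and interferon genes gave no called member. Of 28 members of the NF-kB list, 0 passed the test by limma and 4 had an unadjusted p below 0.05. Il1r1, the receptor for interleukin 1, stood at 2.85 ± 0.538 and 1.26 ± 0.123 FPKM (adjusted p = 0.0554), and was the single member lower when adjusted over the list alone. Nfkbia, the NF-kB inhibitor, stood at 81.9 ± 0.961 and 104 ± 18.4 FPKM (adjusted p = 0.183). Of 44 interferon-response genes, 0 passed by limma and 5 had an unadjusted p below 0.05, and adjusted over the list alone 0 were higher or lower. Irf9 stood at 28.5 ± 1.48 and 33.3 ± 1.44 FPKM, and Ifih1, a sensor of viral RNA, at 5.43 ± 0.510 and 3.97 ± 0.575 FPKM. Of 20 genes of antigen presentation, 0 passed by limma and 2 had an unadjusted p below 0.05, Psmb8 among them (64.2 ± 5.32 and 54.1 ± 4.34 FPKM), with 0 higher or lower when adjusted over the list alone. Camera called none of these 3 lists (adjusted p = 0.473, 0.473 and 0.145).

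TGF-beta signalling genes gave 1 called member. Of 26 members, Klf10, an early transcriptional target of TGF-beta, rose from 67.1 ± 7.41 to 102 ± 5.13 FPKM (log2 change 0.61 ± 0.09, adjusted p = 0.0112), and 25 were not called. Tgfb1 itself stood at 53.7 ± 3.63 and 43.1 ± 1.29 FPKM (adjusted p = 0.0800). Adjusted over the list alone, 1 was higher and 1 lower. Of 15 measured receptors and binding partners of thrombospondins, with no thrombospondin among them, 0 passed by limma over all genes and 5 had an unadjusted p below 0.05, while adjusted over the list alone 1 was higher and 2 were lower. Itgb3, the integrin beta 3 subunit, stood at 13.7 ± 1.81 and 21.8 ± 5.23 FPKM (adjusted p = 0.0934), and Cd47, the thrombospondin receptor that also protects cells from phagocytosis, at 150.1 ± 13.0 and 132 ± 6.25 FPKM (adjusted p = 0.283). Of 27 genes of the megakaryocyte and platelet programme, Selp fell and 26 were not called, and adjusted over the list alone 1 was higher and 2 lower. Pf4, the platelet chemokine, stood at 315 ± 42.3 and 189 ± 48.4 FPKM (adjusted p = 0.0594). Camera called none of the 3 lists (adjusted p = 0.392, 0.205 and 0.349).

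Called genes of the immediate early and handling-stress list were all higher in the libraries labelled knockout, while the median log2 change of the list was 0.0895. Of 24 measured members 5 rose, 0 fell and 19 were not called. Apart from Hspa1b and Egr1, these were Hspa8 (ENSMUSG00000015656, chromosome 9, 40800984 to 40810087), the constitutive HSP70 (log2 change 0.85 ± 0.08, adjusted p = 0.000921), Myc (0.70 ± 0.08, adjusted p = 0.00446) and the HSP40 gene Dnajb1 (0.48 ± 0.09, adjusted p = 0.0332), which lies outside the rule for named genes and was chosen after its values were seen. Dnajb1 lost its call in each of the 6 fits with a library left out (adjusted p up to 0.102). The counts adjusted over the list alone were 8 higher and 1 lower. Camera called the list with its preset correlation (adjusted p = 0.00257), and the call was lost with an estimated one (adjusted p = 0.646 with an estimated correlation). Of 27 genes of the unfolded protein response, Herpud1 rose from 58.2 ± 0.465 to 78.4 ± 4.04 FPKM (adjusted p = 0.0159), and Asns, the asparagine synthetase induced by amino acid shortage, from 27.3 ± 1.27 to 36.7 ± 1.39 FPKM (adjusted p = 0.0284). Pdia3, a protein disulfide isomerase gene that lies near Thbs1, fell from 289.9 ± 6.45 to 229 ± 9.95 FPKM (adjusted p = 0.0401), and 24 were not called. Adjusted over the list alone, 4 were higher and 2 lower. Of 29 p53 targets, Plk2 rose from 5.83 ± 0.108 to 10.9 ± 2.50 FPKM (adjusted p = 0.0377) and 28 were not called, with 2 higher and 0 lower when adjusted over the list alone. Camera called neither of these last lists (adjusted p = 0.284 and 0.205).

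Mitochondrially encoded transcripts leaned lower. Of 13 measured members, 11 had fitted changes below 0, with a median of -0.17, but only mt-Nd3 and mt-Rnr2 passed the test. The 16S ribosomal RNA mt-Rnr2 fell from 2256 ± 205 to 1338 ± 114 FPKM (log2 change -0.75 ± 0.11, adjusted p = 0.0111), and mt-Rnr1 stood at 202 ± 29.2 and 156 ± 4.38 FPKM (adjusted p = 0.112). Of the members that passed, mt-Rnr2 is ribosomal and mt-Nd3 shares its sequence with a pseudogene. The counts adjusted over the list alone were 0 higher and 3 lower. Camera called the list (adjusted p = 0.00209), and the call was lost with an estimated correlation (adjusted p = 0.660 with an estimated correlation), without control library 3 (adjusted p = 0.136) and without knockout-labelled library 1 (adjusted p = 0.0808). Of 54 nuclear-encoded genes of oxidative phosphorylation, 0 passed by limma and 0 had an unadjusted p below 0.05. Sdha, a subunit of complex II, stood at 112 ± 3.5 and 121 ± 2.74 FPKM. Of 26 glycolysis genes and 77 ribosomal protein genes, 0 passed by limma, and 2 and 3 had an unadjusted p below 0.05. Eno1, the glycolytic enolase, stood at 121 ± 4.53 and 136 ± 0.638 FPKM, and Rps19 at 175 ± 17.2 and 206 ± 12.04 FPKM. Of 40 autophagy and lysosome genes, 0 passed by limma and 6 had an unadjusted p below 0.05, 5 of them higher, such as Mcoln1 (10.6 ± 0.956 and 13.2 ± 0.959 FPKM), and 1 lower, Atp6v0d1 (61.5 ± 6.48 and 48.7 ± 6.23 FPKM). Adjusted over each of these 4 lists alone, 0 were higher and 0 lower, and camera called none of them (adjusted p = 0.479, 0.430, 0.205 and 0.149). This depended on the setting: camera called them in the same direction in 3, 2, 6 and 2 of 18 alternatives.

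Cell cycle genes gave a single called member, Pcna. Of 29 S-phase genes, Pcna, the sliding clamp of DNA polymerase, fell from 120.2, 115.4 and 152 FPKM in control libraries 1 to 3 to 77.6, 88.2 and 87.8 FPKM in the libraries labelled knockout (log2 change -0.60 ± 0.11, adjusted p = 0.0309). Pcna lies within 20 Mb of Thbs1, and the pseudogene Pcna-ps2 rose in the same libraries. The other 28 were not called, among them Ung (6.04 ± 0.836 and 4.27 ± 0.329 FPKM) and Cdc45, a part of the replicative helicase (25.1 ± 2.18 and 28.3 ± 1.23 FPKM). Adjusted over the list alone, 0 were higher and 1 lower. Of 30 genes of G2 and M phase, 0 passed by limma and 1 had an unadjusted p below 0.05, Ube2c, at 40.9 ± 0.775 and 48.5 ± 6.95 FPKM, with 0 higher or lower when adjusted over the list alone. Camera called neither list (adjusted p = 0.542 and 0.434).

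Markers of other bone marrow cells were mostly not called. Median log2 changes were below 0 for erythroid (-0.091), T and natural killer cell (-0.065), neutrophil (-0.13) and monocyte, macrophage and dendritic markers (-0.15). The median was above 0 for endothelial markers (0.19). Multipotent progenitor markers, given above, leaned lower too. Of 14 erythroid markers Hbb-bt fell, and Gata1 stood at 25.1 ± 4.99 and 30.3 ± 2.43 FPKM. Of 5 measured T and natural killer cell markers, Nkg7, a granule protein gene, fell from 88.6 ± 14.6 to 54.6 ± 5.85 FPKM (adjusted p = 0.0332). Of 7 endothelial markers, Ramp2 and Sox18 rose, the latter from 7.09 ± 1.49 to 12.7 ± 1.16 FPKM (adjusted p = 0.0344), while Pecam1 stood at 10.6 ± 0.818 and 8.85 ± 0.890 FPKM. Of 6 neutrophil and 8 monocyte, macrophage and dendritic markers, 0 passed by limma and 2 in each list had an unadjusted p below 0.05, Csf3r (30.9 ± 1.01 and 23.9 ± 2.00 FPKM) and Cd68 (11.7 ± 1.66 and 7.40 ± 1.49 FPKM) among them. Adjusted over each list alone, 1 erythroid, 1 T and natural killer, 2 neutrophil and 2 monocyte markers were lower and 2 endothelial markers higher. Camera called none of these 5 lists (adjusted p = 0.154, 0.391, 0.145, 0.167 and 0.145). Stromal, mast cell and B cell lists had 4, 4 and 3 measured members, too few to test as lists, and 0 of these members passed by limma, with 2, 0 and 1 at an unadjusted p below 0.05. Runx2, the single one lower when adjusted over its list alone, stood at 8.24 ± 0.608 and 5.58 ± 0.359 FPKM (adjusted p = 0.0544), Gata2 at 91.6 ± 9.02 and 103 ± 11.6 FPKM, and Cd79b at 28.1 ± 1.36 and 24.4 ± 1.05 FPKM.

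**Figure D2:**
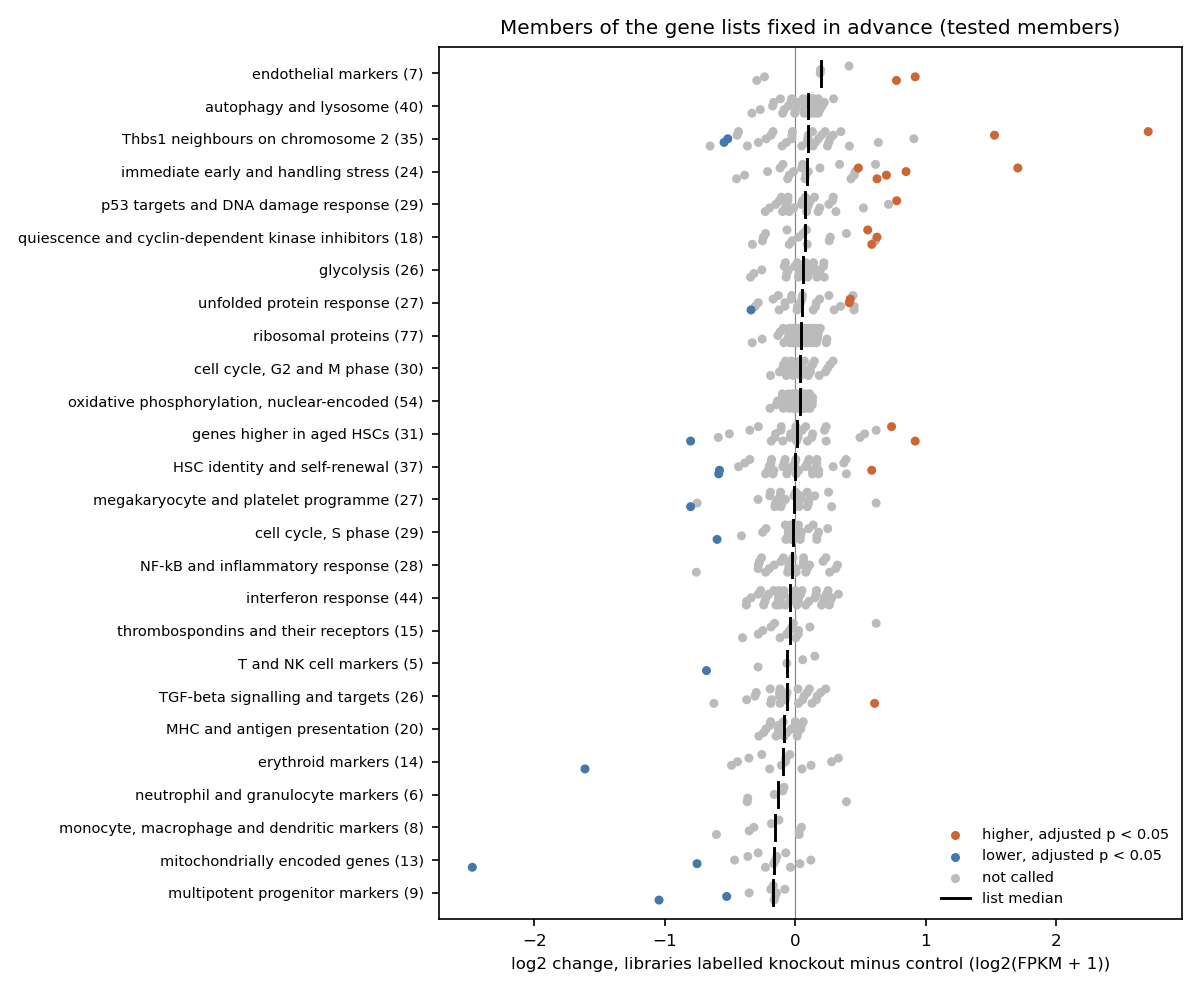
Fitted log2 change (libraries labelled knockout minus control, on log2(FPKM + 1)) of each tested member of the 26 gene lists with at least 5 tested members, with the number tested in parentheses. Coloured points passed an adjusted p of 0.05 over all 12555 genes, black bars are list medians, and most medians lie close to 0.

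Genes beside Thbs1 on chromosome 2 were called more often than genes elsewhere. Within 20 Mb of Thbs1, 21 of 230 tested genes were called (9.1%), 9 of them higher and 12 lower, against 1.42% of all other genes (Fisher's exact test, two-sided, odds ratio 6.97, p = 6.96e-11; neighbouring genes are not independent). The share depended on the width, chosen after seeing the data: 5.4% (2 of 37) within 2 Mb, 13.1% (11 of 84) within 5 Mb, 9.0% (12 of 133) within 10 Mb and 5.3% (24 of 455) within 40 Mb. Of the 35 measured members of the neighbour list fixed in advance, Tmem87a and Rpusd2 rose, and Plcb2, a phospholipase C gene (34.5 ± 1.4 to 23.3 ± 0.896 FPKM, adjusted p = 0.00699), and Snap23, a gene of vesicle fusion (31.8 ± 1.84 to 22.0 ± 2.19 FPKM, adjusted p = 0.0286), fell. The other 31 were not called, and adjusted over the list alone 6 were higher and 4 lower. Camera, which asks for a common direction, did not call the list (adjusted p = 0.324). Without the genes of this stretch, 58 genes were higher and 105 lower, an alternative chosen after seeing the data.

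**Figure D3:**
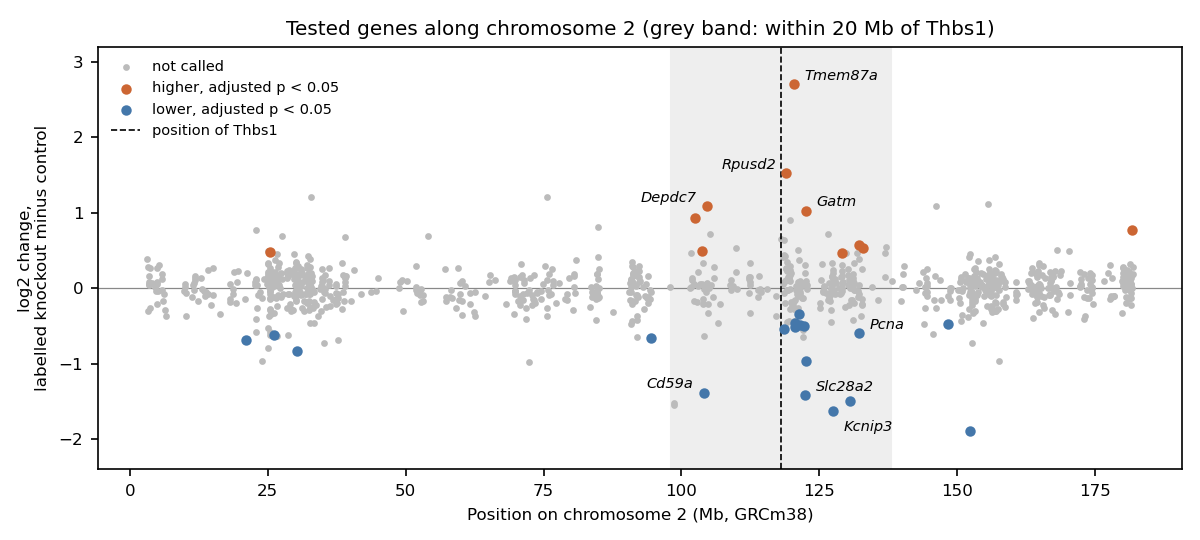
Fitted log2 change of tested genes along chromosome 2 by start position in Mb (GRCm38), with the 20 Mb to each side of Thbs1 shaded and its position dashed. Of the 29 called genes of this chromosome, 21 lie in the shaded stretch.

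With the preset correlation, camera called 3 of the 26 lists tested. With a correlation estimated from the data it called 0, with 1 list at an unadjusted p below 0.05, and the limma test fry for a common direction called 0, with 7 lists at an unadjusted p below 0.05 (lowest adjusted p = 0.0684). Fry's test for change in either direction called 16 lists, without comparing them with other genes. Of 22 called genes followed only as list members, 4 stayed past the threshold with each library left out in turn, Hspa8, Myc and Plcb2 among them, and the other 18 lost it in at least 1 of those 6 fits. Of these 18, 14 lost it in 4 or more, Txnip and Pdia3 in all 6.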

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

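Precision weights from vooma, protein-coding genes alone and leaving out genes near Thbs1 were chosen after seeing the data, and the other settings before. No named gene or gene list that passed its test changed direction in the alternatives that gave it a value, between 14 and 18 of 18; a gene that a setting leaves out has no value there. The 71 higher and 125 lower genes became 8 and 16 with no filter on low values, where 35246 genes were tested in place of 12555, and 24 and 65 with eBayes without trend. The number of higher genes became 112 with a mean of at least 5 FPKM, 112 with array weights, and 127 among protein-coding genes alone. Rescaled to TPM it became 2016, with 128 lower and a median log2 shift of 0.19. A 57-base feature, Gm23935, made up 15.4% to 18.6% of the summed FPKM in the control-labelled libraries and 4.09% to 4.33% in the others, and the sums without it overlap between the groups, so the shift follows from how TPM is built. With libraries left out in turn there were 16 to 38 higher and 43 to 77 lower genes, of which 58 to 91 were among the 196 main calls. Thbs1 ranged from 0.19 to 1.26 on the log2 scale in those fits, past the threshold only without control library 2. The number of called lists, 3, became 11 with no filter, 11 with TPM, 6 with array weights and between 3 and 7 with libraries left out. Some lists without a call in the main fit gained one, such as ribosomal proteins in 6 of 18 alternatives. The antigen presentation and megakaryocyte lists each gained one in 3 of 18. The mitochondrially encoded list had adjusted p between 0.000233 and 0.136 in those fits. With the replicate block, 27 genes were higher and 54 lower, 75 of them among the 196, and the same number of lists, 3, was called. Libraries of the same number share only that number: their deviations from the group means correlated at -0.11, 0.04 and -0.08, and not every library correlated best with its own number. Where no cause is given it was not tested. Depth limits little for a 1 kb gene, since at 1 FPKM it has at least 22.7 reads. Short genes have fewer, and mt-Nd3, with 348 bp of exon, rested on 1 to 47 reads per library.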

Other observations

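The tests of chromosome 2 windows, of the genes near Thbs1 under TPM, of near-identical copies, of small RNA genes outside other genes, of depth, of immediate early genes and of the 6 chaperone-related genes under other scalings were chosen after the result was seen, as were the genes named here outside the fixed rule. Several such genes were lower in the libraries labelled knockout. Cirbp and Rbm3, whose proteins bind RNA and are induced by mild cold, fell by 0.86 and 0.35 on the log2 scale (limma adjusted p = 0.000512 and 0.0391), Cirbp from 77.3 ± 5.51 to 42.0 ± 1.42 FPKM. Cdk6, a kinase that drives stem cells out of quiescence, fell from 20.2 ± 1.67 to 12.8 ± 0.427 FPKM, Lyl1, a basic helix-loop-helix factor of early progenitors, from 29.0 ± 1.02 to 19.5 ± 1.87 FPKM, and Runx3 from 13.2 ± 1.13 to 8.69 ± 0.770 FPKM. Hmox1, which encodes a haem-degrading enzyme, Nqo1, a quinone reductase gene, and Sod1, the cytosolic superoxide dismutase gene, fell by 0.78, 0.39 and 0.40 on the log2 scale. Of the higher genes, Dnaja1, an HSP40 gene, rose from 26.1 ± 1.56 to 41.3 ± 1.95 FPKM, Stip1, a co-chaperone that links HSP70 and HSP90, from 149.9 ± 9.17 to 202 ± 12.3 FPKM, and Nop2, a ribosomal RNA methyltransferase gene, from 44.9 ± 1.35 to 62.1 ± 5.82 FPKM. The polyamine enzyme gene Srm rose from 122 ± 2.71 to 168 ± 7.95 FPKM. With each library left out in turn, Cirbp, Dnaja1 and Hmox1 stayed past the threshold, and the others named here lost it in at least 1 of the 6 fits, Rbm3, Runx3, Nqo1 and Sod1 in all 6.

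With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 196 genes, which 1 of the 10 splits, the real one, reached, and the highest of the others called 1. For gene lists the real split called 3, all 10 splits called at least as many, and the highest of the others called 11. Correlations estimated within lists reached 0.887, above camera's preset of 0.01, and list calls in these splits may come from that.

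The 21 called genes within 20 Mb of Thbs1 stand above the highest count in any of 77 windows of 40 Mb on other chromosomes, 10 on chromosome 11, and 20 of these 21 remain called under median-of-ratios scaling. That scaling moved no gene by more than 0.014 on the log2 scale and so tests little. TPM moved genes by a median of 0.2, and 17 of the 21 kept call and direction, 9 higher and 8 lower. It shifted genes upward by a median of 0.19 and so worked in favour of the 9 rises, which it does not test. Of the 12 falls 8 kept their call, which argues against scaling as the cause of those 8 falls. Under TPM the count in the stretch no longer stood above every other window, with 62 genes of the stretch and up to 82 of another window called. Windows hold different numbers of genes, in the main fit 230 tested in the stretch and 439 in the window of chromosome 11. Shares of called genes were not compared under TPM, so an excess by share stays open there. A candidate explanation is DNA of another mouse strain carried along with the targeted allele, since linked variants would change genes in both directions around it. Near-identical pairs were chosen because the parent fell or the copy rose, so their directions support no explanation: Pcna, Eif3j1 and mt-Nd3 were each lower in all libraries labelled knockout than in all control libraries (3 of 3), and the copies Pcna-ps2, Eif3j2 and Gm28438 rose, Gm28438 from 0.960 ± 0.939 to 11.9 ± 0.258 FPKM. Reads with a variant may have been placed on the copy, but the amounts agree only in part. Of every 1000000 reads, Pcna lost 107 and Pcna-ps2 gained 32.98, Eif3j1 lost 13.37 and Eif3j2 gained 15.92, and mt-Nd3 lost 1.81 and Gm28438 gained 3.76. Moved reads and a change in the transcripts of these pairs cannot be told apart, because the pairs were chosen for the pattern. An effect of the deletion on neighbouring genes stays open and was not tested.

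Gm23935, a 57-base feature on chromosome 16, fell from 64184 ± 10129 to 14234 ± 663 FPKM together with Lars2, Mir6236, Rn7sk, mt-Rnr2 and the 98.2% to 100% identical Gm24187 and Gm24270. Depth does not account for it: depths overlap between the groups (up to 25950000 and from 25760000 reads), while the lowest control library exceeds the highest library labelled knockout 3.95-fold. A candidate explanation is less carry-over of RNA without a poly(A) tail into the libraries labelled knockout. Small RNA genes had a median log2 change of -0.092 and missed the bounds fixed in advance for carry-over, on the median and on the share lower. Missing them decides little, because 172 of those 200 genes overlap another gene whose reads they share. The 28 that do not, a set chosen after the result was seen, had -0.55 (quartiles -0.72 and 0.01). The 2 replication-dependent histone genes at -0.21 are too few. Of the 200 genes 59.0% were lower, with 8 called lower and 0 called higher. Among the 28, 71.4% were lower, with 1 called lower and 0 called higher. Carry-over and a difference between the cells cannot be told apart here, because uncalled members moved both ways and the 28 and the histone genes are few.

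Hspa8, Hspa1b, Hsph1, Dnaja1 and Dnajb1 rose and Cirbp fell, and all 6 stayed past the threshold under TPM, median-of-ratios and quantile scaling (highest adjusted p = 0.0387). Median-of-ratios scaling moved no gene by more than 0.014 on the log2 scale and so tests little. TPM shifted genes upward by a median of 0.19 and so worked in favour of the rises. It did test the fall of Cirbp, which stayed (log2 change -0.67, limma adjusted p = 0.00124). For the rises, the case against scaling rests on quantile normalization alone. These 6 were picked because they changed: Hsp90aa1, a chaperone gene of the handling list, stood at 95.2 ± 12.1 and 98.8 ± 15.6 FPKM (limma adjusted p = 0.894). A candidate explanation is a response to warming or handling while the cells were sorted. The 20 other tested members of the handling list had a median log2 change of 0.077, with 2 called higher and 0 lower, below the bound of 0.33 set from the median of 0.67 of the 4 tested chaperones of that list, Hspa8, Hspa1b, Dnajb1 and Hsp90aa1, and Fos was at 1.18 ± 0.0200 and 0.890 ± 0.209 FPKM. By the rule set for this test, a median under the bound with Fos not higher speaks against an immediate early response to handling. That rule did not use the upper quartile of these 20 members, which at 0.43 lies above the bound, and 2 of them were called higher. Handling and a biological difference between the groups, which was not tested, therefore cannot be told apart.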
